A study of Ictidomys tridecemlineatus with 15 samples.

How the data were processed

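The study measured RNA from the supraoptic nucleus of thirteen-lined ground squirrels in 3 states (active, interbout arousal and torpor), with 5 libraries per state that the design text calls biological replicates. Per the submitters' processing notes, the tools were Trimmomatic 0.39, STAR 2.7.7a, featureCounts of Subread 2.0.1, edgeR 3.38.4 and R 4.2.1. The genome build, the annotation and the strand setting of the read counting are not given in the sources used here, so values of genes that share reads with a neighbour on the other strand are uncertain.

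The deposited table has 16993 genes, of which 24 carry a date in place of a symbol and 3117 an identifier without a symbol. Its per-library values are a signal, deposited as normalised CPM (read counts scaled to the size of the library and by a further scaling factor per library). Per the file headers, the table also holds log2 fold changes against the active state and mean log2 levels, an F score of a joint test of the 3 states, and its p-value with a false discovery rate. In the authors' joint test 2481 genes have a false discovery rate under 0.05. Each library's values are whole multiples of a smallest step, so whole reads were recovered from them, and 100% of values lay within 0.1 read of a whole number. The recovered reads numbered 15844561 to 26113341 per library, with scaling factors from 0.936 to 1.04 (1.01 to 1.04 in active, 0.999 to 1.04 in IBA and 0.936 to 0.990 in torpor). Of the symbols, 87.7% were found in a reference name table, which served only for gene names and neighbours. Vasopressin and oxytocin under their own symbols are not analysed here, and 1 of the 36 gene lists, of mitochondrially encoded genes, was not used here.

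The design assumed counts, and the table held normalised values, so the form of test set out for that case was used: limma-trend (limma 3.58.1 in R 4.3.3, empirical Bayes with trend and robust settings) on log2(value + 1), for genes with a value of at least 1 in at least 5 libraries. This left 15501 genes and removed 1492. All 15 libraries were fitted together without covariates. The tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 35 lists per comparison with 724 measured members, and again with an estimated correlation and with fry. The samples, tests, gene lists, naming rule and the alternative settings named as set beforehand were chosen before the data were examined. Loci of the interval between Fastkd5 and Mrps26 were described because one of them was the most abundant gene in 7 libraries. They were chosen after their values were seen, and their exact tests run over all 252 arrangements of 5 against 5 libraries.

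The genes named per comparison are the 10 with the largest rise and the 10 with the largest fall among genes with a symbol, an adjusted p under 0.05, a mean log2 level of at least 2 and no overlap between the states over their libraries, and up to 4 members with the smallest p in each list described. Mobp in torpor against active and Fos in IBA fall outside this rule and were chosen after their values were seen.

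The procedure was tested on simulated data drawn from the mean levels, library sizes and spread of all 15 libraries, with 200 genes changed in torpor. Of 67 genes changed 1.5-fold limma-trend recovered 44.8%, of 67 changed 2-fold 86.6% and of 66 changed 3-fold 100%. It called 164 genes, of which 10 (6.1%) were unchanged, against 4.3% for edgeR, 14.1% for DESeq2 and 6.1% for limma-voom. In an unchanged comparison none of these 4 tools called a gene, and of 35 lists only the changed list was called. The simulated genes were drawn independently of each other, so this does not test list calls among correlated genes. In the measured data the estimated correlation was 0.40 for oxidative phosphorylation and 0.63 for ribosomal proteins. At this depth and spread, changes below 2-fold were often missed.

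The alternative settings set beforehand were pseudocounts of 0.1 and 5, no filter on low values, only the 10 libraries compared, a replicate block, each replicate left out in turn, and, on the recovered reads, edgeR 4.0.16 with median-of-ratios scaling, a stricter filter or no filter, DESeq2 1.42.0 and limma-voom with quality weights. Alternatives added after the data were seen were edgeR on the recovered reads with its default settings, median-of-ratios and library-size scaling in limma, leaving out torpor libraries 4 and 5, the mean log2 level of the oligodendrocyte markers as a covariate, and leaving out unnamed loci and dates. Log2 fold changes were also compared with those deposited by the authors: across genes, which are not independent replicates, r was 0.963 in torpor and 0.961 in IBA, and all 3018 and 202 called genes had the same sign.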

Results

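RNA was sequenced from the supraoptic nucleus of thirteen-lined ground squirrels, the hypothalamic nucleus whose large neurosecretory neurons release vasopressin and oxytocin into the blood. The 15 libraries covered 3 physiological states with 5 biological replicates each: active animals outside the hibernation season, animals in torpor, and hibernating animals in interbout arousal (IBA), the brief return to a warm body between bouts of torpor. The nuclei were dissected by hand from coronal brain slices, so neurons, glia and vessel cells were sequenced together. The reads counted per library, recovered from the deposited values, numbered 15844561 to 21216931 in the active state, 19320883 to 23621875 in IBA and 21570371 to 26113341 in torpor. Levels are normalised CPM (read counts scaled to the size of the library and by a further factor per library, from 0.936 to 1.04), given as mean ± SD with n = 5 per state. Changes are differences of mean log2(value + 1) with their standard errors, and adjusted p-values come from limma-trend over the 15501 genes that passed the filter on low values. These p-values reflect the spread between libraries.

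Active libraries lay apart from the others on the main axis of variation, where IBA and torpor overlapped. The leading principal component carried 28.4% of the variance and ran from −51.1 to −16.2 in active libraries, from −1.62 to 19.7 in IBA and from −2.28 to 39.3 in torpor. Active library 4 lay at −51.1, apart from the other active libraries, which reached down to −20.6. Torpor libraries 4 and 5 lay highest, at 39.3 and 34.9. Torpor library 2 lay alone on the next component (15.7% of the variance), at −47.5.

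**Figure D1:**
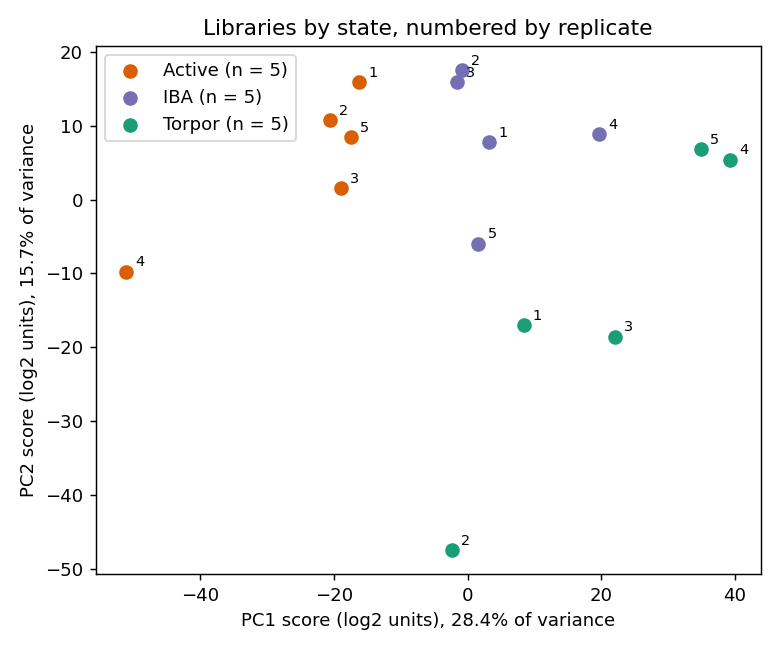
Principal component scores of the 15 libraries on log2 levels, 5 per state, with the replicate number beside each point and both axes in log2 units. Torpor library 2 lies at −47.5 on the vertical axis and active library 4 at −51.1 on the horizontal axis.

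The most abundant transcript in 7 of the 15 libraries was LOC101970427, a protein-coding locus without a gene symbol. It lies between Fastkd5 and Mrps26 in the reference name table, as do LOC101967640 and LOC101967926, which were also abundant. LOC101970427 stood at 19850 ± 14070 normalised CPM in torpor, 7378 ± 4048 in IBA and 3305 ± 1545 in the active state (SD, n = 5). Its log2 fold change between torpor and the active state was 2.29 ± 0.73 (SE) with a limma adjusted p of 0.0430. A two-sided exact permutation test on this locus alone gave p = 0.0397, or 0.143 after Benjamini-Hochberg adjustment over the 9 tests of the interval, whose smallest possible p was 0.00794. The limma call ended when any of 8 libraries was left out, with adjusted p from 0.0558 to 0.108: active library 1, 2, 4 or 5, or torpor library 2, 3, 4 or 5. It held without active library 3 (0.0475) and without torpor library 1 (0.00545), which stood at 2361, within the active range of 880 to 4983. Over all alternatives the adjusted p ranged from 4.01e-05 to 0.270. The locus did not pass in the other comparisons, where its log2 fold change was 1.14 ± 0.73 in IBA against active and 1.16 ± 0.73 in torpor against IBA (adjusted p = 0.418 and 0.413). LOC101967640 stood at 3708 ± 1864 in torpor and 3295 ± 488 in the active state, and LOC101967926 at 5476 ± 2389 and 6115 ± 896, with adjusted p = 0.970 and 0.514. In IBA, LOC101967926 stood at 3627 ± 780, below every active library, with exact p = 0.00794, the smallest the test can give, 0.0714 after adjustment over the 9 tests and a limma adjusted p of 0.175. Reads of near-identical copies can be split between such loci, so their levels are uncertain.

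**Figure D2:**
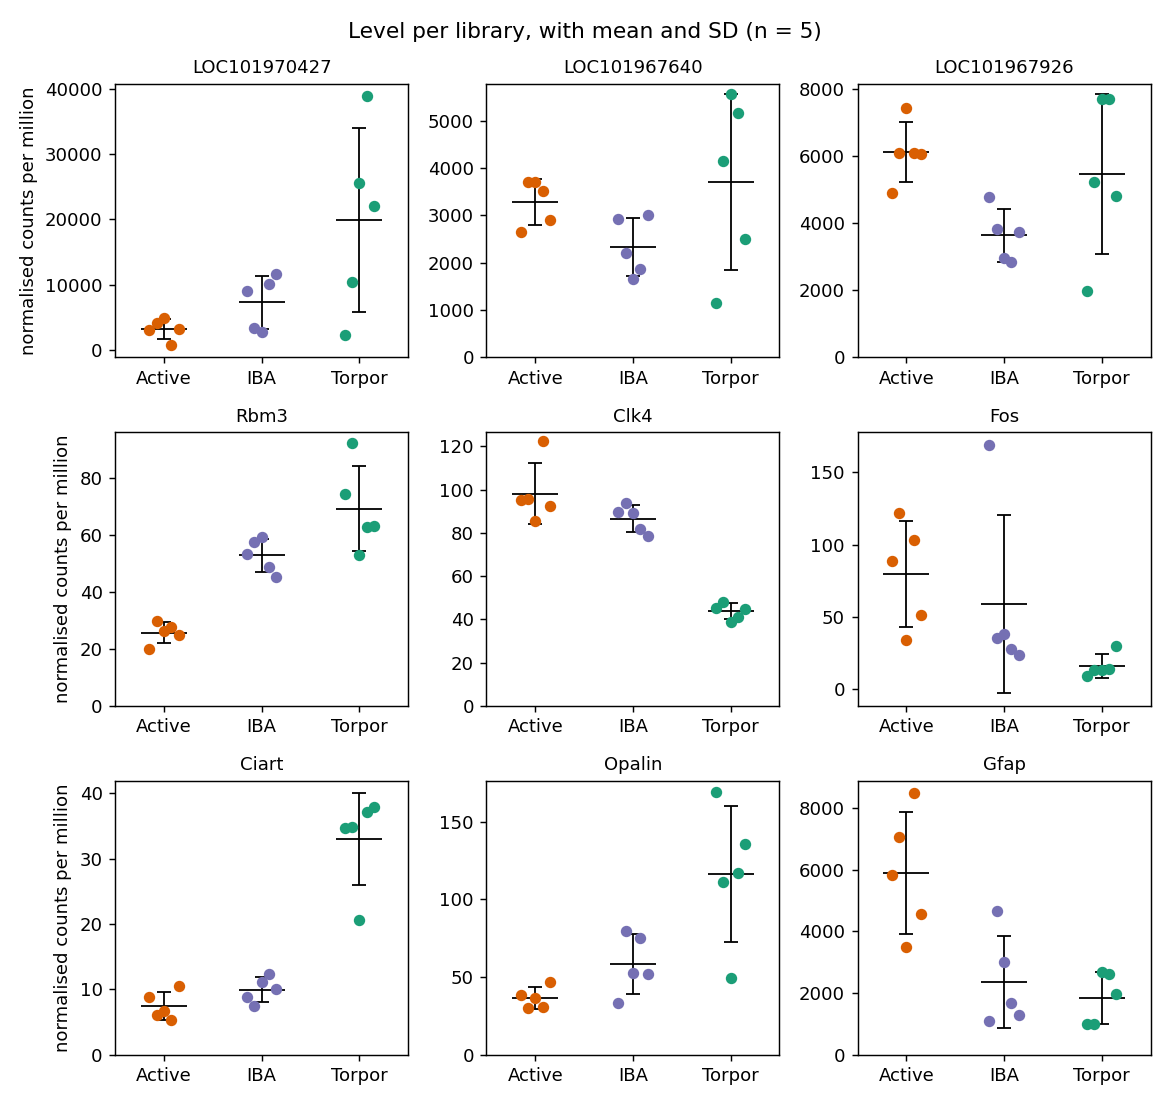
Normalised CPM of 9 genes in each of the 15 libraries, coloured by state, with the mean and SD of the 5 libraries per state as lines. LOC101970427 averaged 19850 in torpor and 3305 in the active state, while Clk4 averaged 43.6 and 98.1.

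Torpor was compared with the active state to find which transcripts of the nucleus differ in the cold, inactive phase of hibernation. Ciart, a repressor of the circadian clock, rose 4.03-fold, to 33.0 ± 7.06 normalised CPM from 7.47 ± 2.11 (n = 5). Rbm3, a cold-inducible RNA-binding protein, rose 2.60-fold, to 69.2 ± 14.97 from 25.7 ± 3.67. Fos, an immediate early gene induced by neuronal activity, fell by 2.22 on the log2 scale, to 16.0 ± 8.18 from 79.8 ± 36.5, and Gfap, the intermediate filament of astrocytes, fell by 1.74, to 1847 ± 838 from 5887 ± 1985. Markers of oligodendrocytes shifted upward with a median log2 fold change of 1.20, and those of endothelial and mural cells shifted downward with medians of −0.31 and −0.33 (camera with a preset correlation; adjusted p = 0.583 for each of the 3 lists with an estimated correlation).

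In this comparison 3018 of the 15501 genes tested passed an adjusted p of 0.05, of which 1508 were higher in torpor and 1510 lower. With the reads scaled by library size alone the split was 1051 higher and 2274 lower. The states did not overlap over their libraries for 1890 genes (12.2%), against 0.79% by chance. Among the 10 genes with the largest rise, Lsm4, a subunit of the ring complex that binds U6 RNA and decaying mRNA, rose by 2.65 ± 0.54, to 52.4 ± 31.0 from 5.94 ± 1.46 (adjusted p = 0.00471), with torpor libraries spread from 10.0 to 82.3. C1qtnf4, a secreted C1q/TNF-related protein, rose by 2.21 ± 0.31 and Nop53, a ribosome assembly factor, by 2.03 ± 0.33 (adjusted p = 3.43e-04 and 0.00127). The others were Mag, Ciart, Znf428, Gdf10, Abtb1, Ndufaf8 and Cldn11, with rises from 1.71 to 2.08. Lsm4, C1qtnf4, Nop53, Znf428, Abtb1, Ndufaf8 and LOC101970427 shared a pattern over libraries of the same state. Each stood higher in IBA libraries 1, 4 and 5 than in 2 and 3, and lowest in torpor library 1 among the torpor libraries. Lsm4 stood at 21.4, 42.4 and 36.7 in IBA libraries 1, 4 and 5 and at 8.57 and 10.4 in 2 and 3. The pattern was not limited to these genes: Pcsk1n, Rab3a, Nefl and Tubb3 also followed it. These rises may therefore not be separate changes, and what the genes share was not tested. Among the 10 largest falls, Kctd21, an adaptor of cullin 3 ubiquitin ligases, fell by 2.00 to 2.14 ± 0.586 from 11.4 ± 0.868, and Banp, a DNA-binding protein of the nuclear matrix, fell by 1.93 to 10.7 ± 2.47 from 43.0 ± 6.41 (adjusted p = 1.46e-06 for each). Fos, Azgp1, CUNH10orf10, Gfap, Cxcr4, Olfml2b, Gcnt3 and Htr1e completed the list, with log2 fold changes from −2.22 to −1.56. All 20 of these calls held with any of the 10 libraries left out.

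Genes of RNA processing and of the circadian clock changed in opposite directions within their lists. Of 21 measured cold-inducible RNA-binding proteins and splicing factors, 2 rose, 8 fell and 11 did not pass, and 3 rose and 9 fell adjusted over the list alone. Rbm3 rose by 1.38 ± 0.14 (adjusted p = 1.23e-05) and Cirbp, the other cold-inducible member, by 0.89 ± 0.12 (adjusted p = 2.24e-04). The kinases of splicing factors Clk4 and Clk1 fell by 1.14 ± 0.10 and 1.28 ± 0.14 (adjusted p = 3.27e-06 and 2.46e-05). As a whole this list did not pass the camera test (median −0.14, adjusted p = 0.0912). Of 19 clock genes, 3 rose and 3 fell, and 4 rose and 3 fell adjusted over the list alone. Beside Ciart, the nuclear receptor genes Nr1d1 and Nr1d2 moved apart, the former up by 0.84 ± 0.16 and the latter down with a log2 fold change of −0.47 ± 0.11 (adjusted p = 0.00188 and 0.00752), and Bhlhe40 rose by 0.40 ± 0.11 (adjusted p = 0.0150). The clock list had a median of 0.18 and an adjusted p of 0.376. Time of day of collection was not part of the model, so a difference in it between the states was not tested. Of 20 immediate early genes, 2 rose and 4 fell, and 4 rose and 7 fell adjusted over the list alone (median −0.49, adjusted p = 0.106). Fos and Nr4a2, a nuclear receptor induced by activity, fell, the latter by 1.22 ± 0.30 to 3.46 ± 1.74 from 9.01 ± 2.24 (adjusted p = 0.0107).

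Transcripts of respiration and translation shifted upward. Of 56 nuclear-encoded subunits of oxidative phosphorylation, 15 rose and none fell, and 15 rose adjusted over the list alone. The median was 0.20 and the camera adjusted p 1.03e-06 with a preset correlation, and adjusted p = 0.583 with an estimated correlation. Ndufa10 and Ndufa11, subunits of complex I, rose by 0.72 ± 0.09 and 0.69 ± 0.11 (adjusted p = 1.30e-04 and 6.15e-04), and Sdhb of complex II rose by 0.44 ± 0.10 (adjusted p = 0.00680). Of 75 cytosolic ribosomal proteins, 5 rose and none fell, and 2 rose adjusted over the list alone, with 68 members above 0. This list had a median of 0.12 and an adjusted p of 0.00194, and adjusted p = 0.619 with an estimated correlation. Rpl13 rose to 61.9 ± 2.87 from 47.9 ± 5.17 (0.37 ± 0.09, adjusted p = 0.00857) and Rpl38 by 0.44 ± 0.11 (adjusted p = 0.0118). Without torpor library 2, the library alone on the second component, the ribosomal list had an adjusted p of 0.151. With reads scaled by library size the medians were 0.12 for oxidative phosphorylation and 0.04 for ribosomal proteins.

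Chaperone transcripts shifted downward. Of 22 heat shock chaperones, 8 fell and none rose, and 11 fell adjusted over the list alone (median −0.41, adjusted p = 0.00109, and adjusted p = 0.583 with an estimated correlation). Stip1, the co-chaperone that links the Hsp70 and Hsp90 families, fell by 0.84 ± 0.13 to 251 ± 47.5 from 447 ± 57.8 (adjusted p = 5.81e-04). Chordc1 and Dnaja1 fell by 0.68 ± 0.12 and 0.68 ± 0.15, and Hspa1b by 0.87 ± 0.21 (adjusted p = 0.00132, 0.00583 and 0.00771). Of 22 genes of the unfolded protein response in the endoplasmic reticulum, 6 fell and none rose, and 7 fell adjusted over the list alone (median −0.17, adjusted p = 0.0302, and adjusted p = 0.619 with an estimated correlation). Xbp1, a transcription factor of this response, fell by 0.68 ± 0.12 (adjusted p = 0.00131), Herpud1 by 0.48 ± 0.09 and Atf4 by 0.50 ± 0.11 (adjusted p = 0.00136 and 0.00467). The call of the unfolded protein list ended without active library 3, torpor library 1 or torpor library 5 (adjusted p from 0.0597 to 0.0958). With the mean level of the oligodendrocyte markers in the model, the median was −0.07 for the heat shock list and 0.12 for the unfolded protein list, and both calls ended (adjusted p = 0.343 and 0.608).

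Markers of several cell types differed between torpor and the active state. Of 13 oligodendrocyte markers, 9 rose and none fell, and 11 rose adjusted over the list alone (median 1.20, adjusted p = 4.99e-05, and adjusted p = 0.583 with an estimated correlation). Opalin, a myelin membrane protein, rose to 116 ± 43.7 from 36.4 ± 7.002 (1.56 ± 0.29, adjusted p = 0.00244), and Mog and Gjb1 rose by 0.99 ± 0.22 and 1.24 ± 0.29 (adjusted p = 0.00542 and 0.00798). Mobp, another myelin gene, had a log2 fold change of −0.17 ± 0.27 (adjusted p = 0.707). The mean log2 level of these markers ranged from 6.18 to 6.998 in active libraries and from 6.84 to 8.18 in torpor, with torpor libraries 4 and 5 highest at 7.94 and 8.18. Of 9 oligodendrocyte precursor markers, 4 rose, and adjusted over the list alone 4 rose and 1 fell (median 0.94, adjusted p = 0.0161, and adjusted p = 0.583 with an estimated correlation). Olig1 and Olig2, transcription factors of this lineage, rose by 1.66 ± 0.32 and 1.39 ± 0.29 (adjusted p = 0.00324 and 0.00409). Bcas1 and Neu4 were the others that rose, while Pdgfra and Cspg4, also on the list, did not pass over all genes. With the oligodendrocyte marker level in the model the precursor median was 0.10 (camera adjusted p = 0.857). The precursor shift therefore cannot be told apart here from that of the oligodendrocyte markers. Of 13 endothelial markers, 3 fell, also adjusted over the list alone (median −0.31, adjusted p = 0.0113, and adjusted p = 0.583 with an estimated correlation). Flt1, a receptor for vascular growth factors, fell by 0.81 ± 0.09 and Ocln, a tight junction protein, by 0.79 ± 0.17 (adjusted p = 6.00e-05 and 0.00500). Of 11 mural cell markers, 4 fell, and 5 fell adjusted over the list alone (median −0.33, adjusted p = 0.0403, and adjusted p = 0.583 with an estimated correlation). Kcnj8 fell by 1.01 ± 0.19 and Tagln by 1.13 ± 0.25 (adjusted p = 0.00186 and 0.00544). The mural list lost its call without active library 2 or 4 or torpor library 2 or 3 (adjusted p from 0.0502 to 0.200) and under scaling by library size (0.0759). Of 11 astrocyte markers, only Gfap passed. That list had a median of 0.01, a mean of −0.20 and an adjusted p of 0.445. Of 13 neuron markers, 3 rose and 1 fell (median 0.30, adjusted p = 0.106), among them Nefl, up by 0.53 ± 0.14, and Tubb3, up by 0.80 ± 0.22 (adjusted p = 0.0150 and 0.0173). Of 11 microglia markers, 2 rose (median 0.27, adjusted p = 0.0747), among them C1qa at 3.95 ± 1.73 against 0.800 ± 0.335 (adjusted p = 9.91e-04).

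Markers of neighbouring nuclei and genes of neuropeptides, release and osmotic regulation were described by 5 lists, of which 2 passed. Of 15 markers of neighbouring hypothalamic nuclei, 5 rose and none fell, also adjusted over the list alone (median 0.62, adjusted p = 0.00741, and adjusted p = 0.583 with an estimated correlation). These genes mark tissue around the supraoptic nucleus, so a change in the nucleus and a wider dissection cannot be told apart here. The somatostatin gene Sst rose to 398 ± 197 from 159 ± 64.7 (1.27 ± 0.33, adjusted p = 0.0150) and Pomc to 7.89 ± 3.06 from 3.85 ± 0.636 (0.81 ± 0.21, adjusted p = 0.0131). Of 13 magnocellular neuropeptide genes, 2 rose, and 5 rose adjusted over the list alone, and the list did not pass (median 0.46, adjusted p = 0.0529). Tac1, which encodes substance P, rose by 1.08 ± 0.29 and Cck, which encodes cholecystokinin, by 0.99 ± 0.27 (adjusted p = 0.0167 and 0.0168). Of 27 synaptic vesicle and release genes, 4 rose and 1 fell, also adjusted over the list alone (median 0.27, adjusted p = 0.0302, and adjusted p = 0.587 with an estimated correlation). Napb, a factor in the recycling of SNARE complexes, rose by 0.44 ± 0.11 (adjusted p = 0.0118), and Vamp1, a vesicle SNARE, by 0.56 ± 0.16 (adjusted p = 0.0239). The list lost its call without active library 4 (adjusted p at most 0.132) or torpor library 1, and Vamp1 without active library 2 or 4 or torpor library 4 or 5 (from 0.0523 to 0.0613). With the oligodendrocyte marker level in the model the list's median was 0.04 and its call ended (adjusted p = 0.593). Of 23 genes of peptide processing and dense-core vesicles, 4 rose, also adjusted over the list alone (median 0.04, adjusted p = 0.399), among them Pcsk1n, an inhibitor of the prohormone convertase Pcsk1, at 774 ± 331 against 234 ± 74.7 (1.65 ± 0.38, adjusted p = 0.00891). Pcsk1n and Rab3a, another of those that rose, followed the library pattern of Lsm4. Pcsk1n stood at 274 in torpor library 1, within the active range of 113 to 287, so these rises may not be separate changes. Of 18 genes of the osmotic response and of magnocellular regulation, 4 fell, and adjusted over the list alone 1 rose and 4 fell (median 0.03, mean −0.07, adjusted p = 0.410). Slc5a3, the myo-inositol transporter that cells induce in hypertonic surroundings, fell by 0.92 ± 0.10 to 42.1 ± 3.57 from 80.8 ± 10.8 (adjusted p = 3.71e-05). Pou3f2, a transcription factor of magnocellular development, fell by 0.77 ± 0.14 (adjusted p = 0.00125).

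Over all alternatives, the lowest adjusted p of the 10 lists called in this comparison lay between 1.19e-11 and 0.00761 and the highest between 0.583 and 0.861. With torpor libraries 4 and 5 left out, 2200 genes passed, of which 1731 were among the 3018. The precursor, neighbouring nuclei, synaptic vesicle and unfolded protein lists then lost their calls (medians 0.28, 0.39, 0.10 and −0.09, adjusted p = 0.109, 0.0997, 0.0997 and 0.159). Of the lists that kept theirs, the median moved to −0.22 for heat shock chaperones (adjusted p = 0.0171), 0.80 for oligodendrocyte markers (0.00247), 0.22 for ribosomal proteins (2.96e-08) and −0.55 for mural markers (0.00247), where over the 15 libraries the adjusted p with an estimated correlation was 0.583, or 0.619 for ribosomal proteins. With the oligodendrocyte marker level in the model, 819 genes passed and 655 of them were among the 3018, and the precursor and neighbouring nuclei lists lost their calls (medians 0.10 and 0.47, adjusted p = 0.857 and 0.608). The marker level itself differed between the states, so a call that ended in this model need not rest on oligodendrocytes. For LOC101970427 the log2 fold change moved only from 2.29 to 2.24, while the limma adjusted p went from 0.0430 to 0.270.

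**Figure D3:**
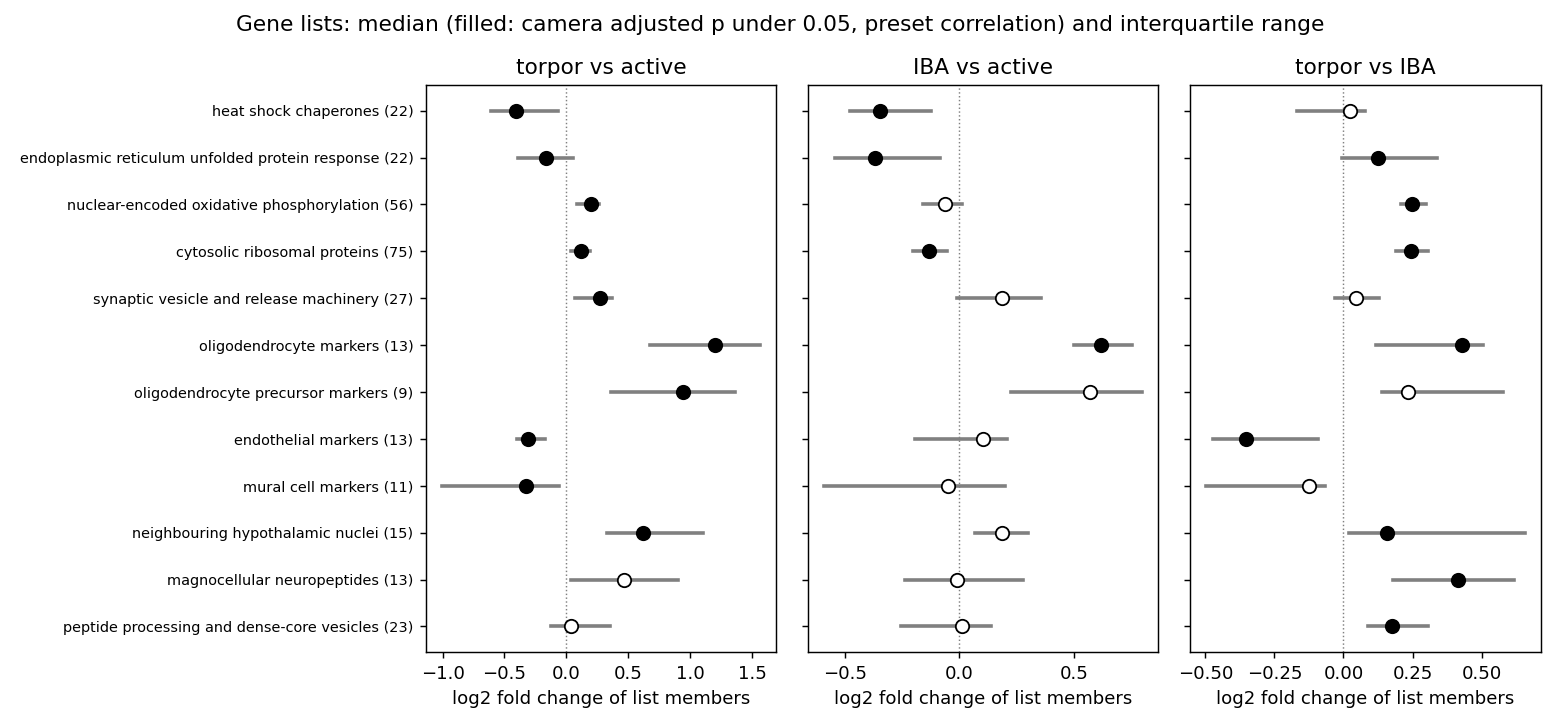
Median log2 fold change of the members of 12 gene lists in each comparison, with the interquartile range as a bar and the number of measured members in brackets; filled points mark a camera adjusted p under 0.05 with a preset correlation. Oligodendrocyte markers have medians of 1.20, 0.62 and 0.43 in the 3 comparisons.

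Interbout arousal was compared with the active state to find what differs between warm animals inside and outside the hibernation season. Rbm3 rose 2.02-fold, to 52.8 ± 5.89 normalised CPM from 25.7 ± 3.67 (n = 5, 1.01 ± 0.14, adjusted p = 0.00193). Dnajb9, a chaperone of the endoplasmic reticulum, fell by 0.73 ± 0.11 to 140 ± 22.4 from 231 ± 23.4 (adjusted p = 0.00399). Slc14a1, a urea transporter, fell by 1.06 ± 0.16 to 148 ± 50.9 from 299 ± 26.8, and Kctd21 fell by 1.19 ± 0.16 to 4.48 ± 0.882 from 11.4 ± 0.868 (adjusted p = 0.00399 and 0.00193). These calls held with any of the 10 libraries left out.

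Here 202 genes passed, 93 higher and 109 lower in IBA, and 3046 had an unadjusted p under 0.05. The states did not overlap over their libraries for 1086 genes (7%), against 0.79% by chance. Among the 10 largest rises, Nrip3 rose by 1.25 ± 0.19 to 18.3 ± 4.67 from 7.03 ± 1.64 (adjusted p = 0.00399). Slc45a3 rose most, by 1.95 ± 0.35 (adjusted p = 0.0204), and Lcn15, Nop53, Agtrap, C1qtnf4, Tmc6, Tab1, Klk6 and Parvb rose by 1.12 to 1.74. Among the 10 largest falls, Znf331, a zinc finger gene, fell by 1.14 ± 0.14 to 85.3 ± 17.4 from 187 ± 22.7 (adjusted p = 8.73e-04), and Colgalt2, a collagen galactosyltransferase, by 1.08 ± 0.17 (adjusted p = 0.00515). Gfy, Olfml2b, Tpm2, Crem, the cAMP-responsive element modulator, Grpr, the receptor for gastrin-releasing peptide, and Id3 had log2 fold changes from −1.93 to −0.93. Of these 20 calls 5 held with any library left out. Without IBA library 4 the other 15 ended, with adjusted p from 0.0640 to 0.126, and each of the other 9 libraries ended at least 1 of them.

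Genes of protein folding were the clearest group in IBA. Of 22 genes of the unfolded protein response, 6 fell and none rose, and 13 fell adjusted over the list alone (median −0.37, adjusted p = 6.35e-09, and adjusted p = 0.703 with an estimated correlation). Beside Dnajb9, Xbp1 fell by 0.63 ± 0.12 and Atf4 by 0.56 ± 0.11 (adjusted p = 0.0204 and 0.0208), and these 2 calls ended without active library 3 or IBA library 4 (adjusted p from 0.0518 to 0.0692). Of 22 heat shock chaperones, 2 fell and none rose, and 9 fell adjusted over the list alone (median −0.35, adjusted p = 6.69e-06, and adjusted p = 0.703 with an estimated correlation). Those past the threshold over all genes were Stip1, down by 0.65 on the log2 scale with a log2 fold change of −0.65 ± 0.13, and Hsp90aa1, at 591 ± 83.4 against 1009 ± 169 (adjusted p = 0.0242 and 0.0345). Both ended without active library 3 or 4 or IBA library 3 or 4, and Hsp90aa1 also without active library 1 or 2 or IBA library 1 or 2 (adjusted p from 0.0538 to 0.0906). With the oligodendrocyte marker level in the model the medians were −0.18 for the unfolded protein list and −0.19 for the heat shock list.

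Ribosomal protein and oligodendrocyte transcripts shifted without single genes past the threshold. Of 75 ribosomal protein genes none rose or fell, also adjusted over the list alone, while 64 were below 0 (median −0.13, adjusted p = 3.64e-05, and adjusted p = 0.886 with an estimated correlation). With the oligodendrocyte marker level in the model the ribosomal median was −0.05 and the call ended (adjusted p = 0.152). Rpl23a and Rpl24 had log2 fold changes of −0.34 ± 0.10 and −0.38 ± 0.12 (adjusted p = 0.0912 and 0.108). Of 13 oligodendrocyte markers none passed over all genes and 5 rose adjusted over the list alone (median 0.62, adjusted p = 4.96e-04, and adjusted p = 0.886 with an estimated correlation). Mag, the myelin-associated glycoprotein, stood at 82.0 ± 27.5 against 30.3 ± 14.3 and Ugt8, an enzyme of myelin lipid synthesis, at 96.0 ± 23.4 against 67.0 ± 11.2 (adjusted p = 0.115 and 0.0864). The markers' mean log2 level ranged from 6.68 to 7.63 in IBA.

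Few single neuronal and osmotic genes passed in IBA. Of 27 synaptic vesicle and release genes none passed, also adjusted over the list alone, while 20 were above 0 (median 0.19, adjusted p = 0.0514). Of 13 magnocellular neuropeptide genes none passed (median −0.01, mean 0.07, adjusted p = 0.934), and of 23 genes of peptide processing none passed over all genes, while 1 rose and 4 fell adjusted over the list alone (median 0.01, mean −0.02, adjusted p = 0.462). Pcsk1, the prohormone convertase, stood at 472 ± 150 against 969 ± 209 (adjusted p = 0.0679). Of 18 osmotic genes, Slc5a3 fell by 0.54 ± 0.10 (adjusted p = 0.0204), a call that ended without active library 4 or IBA library 3 or 4 (from 0.0524 to 0.0647), and the list had a median of 0.05 (adjusted p = 0.934). Of 20 immediate early genes none passed (median −0.13, adjusted p = 0.476). Fos was at 169 in IBA library 1 and between 23.5 and 38.4 in the other IBA libraries. Of 21 cold-inducible and splicing genes Rbm3 passed, and adjusted over the list alone 2 rose and 8 fell (median −0.21, adjusted p = 0.0514). Of 19 clock genes none passed, and 1 rose and 1 fell adjusted over the list alone (median 0.06, adjusted p = 0.736). Among astrocyte markers Fgfr3 fell by 0.55 ± 0.13 (adjusted p = 0.0453), a call that ended without any of 8 libraries (active 1 to 4, IBA 1, 3, 4 or 5; adjusted p from 0.0744 to 0.111), and Gfap stood at 2349 ± 1491 against 5887 ± 1985 (adjusted p = 0.0912).

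The count of 202 depended on single libraries more than the other counts did. It was 26 without IBA library 4, 57, 64, 71 and 91 without active libraries 4, 3, 2 and 1, and 60, 98 and 118 without IBA libraries 3, 1 and 5. With the oligodendrocyte marker level in the model 19 genes passed. Over all alternatives, the lowest adjusted p of the 4 lists lay between 9.24e-12 and 1.60e-05 and the highest between 0.703 and 0.907.

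Torpor was compared with interbout arousal to find what differs between the cold and the warm phase within hibernation. Ciart rose 3.08-fold in torpor, to 33.0 ± 7.06 normalised CPM from 9.96 ± 1.93 (n = 5, 1.62 ± 0.19, adjusted p = 1.91e-04). Clk4 and Clk1 fell by 0.97 ± 0.10 and 0.98 ± 0.14, to 43.6 ± 3.71 from 86.6 ± 6.16 and to 31.5 ± 5.90 from 62.5 ± 3.80 (adjusted p = 4.15e-05 and 0.00113). Slc19a3, a thiamine transporter, fell by 1.66 ± 0.14 to 4.78 ± 0.550 from 17.4 ± 2.97 (adjusted p = 4.40e-06). Subunits of oxidative phosphorylation and ribosomal proteins shifted upward with medians of 0.25 and 0.24, and endothelial markers shifted downward with a median of −0.35 (camera with a preset correlation; adjusted p = 0.546, 0.708 and 0.708 with an estimated correlation).

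Here 455 genes passed, 149 higher and 306 lower in torpor. Without torpor library 1, 666 passed, 321 higher and 345 lower. With scaling by library size 859 passed, 92 higher and 767 lower. The states did not overlap over their libraries for 893 genes (5.8%), against 0.79% by chance. Beside Ciart, the 10 largest rises included Pcgf6, a polycomb subunit, up by 1.08 ± 0.18, Tpgs1, a subunit of a tubulin-modifying enzyme, up by 0.87 ± 0.14, and Stmn4, a microtubule regulator, up by 0.73 ± 0.12 (adjusted p = 0.00398, 0.00252 and 0.00313). Gdf10, Rps6kl1, Nfe2l3, Hes1, Cep76 and CUNH19orf60 rose by 0.73 to 1.08. Among the 10 largest falls, Tmem41a fell by 2.45 ± 0.37 to 3.02 ± 3.04 from 18.3 ± 6.40 (adjusted p = 0.00301), and Kcnj2, an inwardly rectifying potassium channel, by 1.31 ± 0.22 (adjusted p = 0.00466). Arc, Siglecl1, Znf366, Znf526, Robo4, Nabp1 and Znf646 had log2 fold changes from −1.86 to −1.28. Of these 20 calls 14 held with any of the 10 libraries left out. The call of Cep76 ended without IBA library 2 (adjusted p = 0.0580), and those of Gdf10, Nfe2l3, Hes1, Arc and Robo4 ended without 5 to 10 of the libraries, each of the 10 libraries ending at least 1 of them (adjusted p from 0.0505 to 0.112).

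Of 56 subunits of oxidative phosphorylation, 3 rose and none fell, and 39 rose adjusted over the list alone, with 55 above 0 (median 0.25, adjusted p = 1.24e-18, and adjusted p = 0.546 with an estimated correlation). Ndufa4 rose to 731 ± 69.3 from 561 ± 30.9 (0.38 ± 0.08, adjusted p = 0.0247), Ndufa11 by 0.47 ± 0.11 and Ndufb11 by 0.32 ± 0.08 (adjusted p = 0.0286 and 0.0335). Of 75 ribosomal proteins, 2 rose and none fell, and 34 rose adjusted over the list alone, with 73 above 0 (median 0.24, adjusted p = 1.82e-18, and adjusted p = 0.708 with an estimated correlation). Rps15 rose by 0.43 ± 0.10 and Rpl28 by 0.34 ± 0.09 (adjusted p = 0.0319 and 0.0433). Each of these 5 single-gene calls ended without IBA library 2 or 3 or torpor library 2 or 3, and some of them without IBA library 1, 4 or 5 or torpor library 4 (adjusted p from 0.0529 to 0.120). The library scaling moved these list medians to 0.16 and 0.15 when reads were scaled by library size, and without torpor libraries 4 and 5 they were 0.31 and 0.34.

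Of 13 endothelial markers, 4 fell and none rose, and 5 fell adjusted over the list alone (median −0.35, adjusted p = 6.08e-04, and adjusted p = 0.708 with an estimated correlation). Flt1 fell by 0.47 ± 0.09 (adjusted p = 0.0141) and this call held with any library left out. Ocln, Robo4 and Tek fell by 0.68 ± 0.17, 1.32 ± 0.33 and 0.49 ± 0.13 (adjusted p = 0.0433, 0.0448 and 0.0470). These 3 calls ended without IBA library 1, 2 or 3 or torpor library 2, 3 or 5, and some of them without IBA library 4 or 5 or torpor library 1 or 4 (adjusted p from 0.0505 to 0.121). Of 11 mural markers 2 fell, also adjusted over the list alone, and the list did not pass (median −0.13, adjusted p = 0.0971). Of 13 oligodendrocyte markers none passed, also adjusted over the list alone (median 0.43, adjusted p = 0.0308, and adjusted p = 0.708 with an estimated correlation). Opalin stood at 116 ± 43.7 against 58.5 ± 19.1 and Mbp, the myelin basic protein gene, at 1876 ± 1786 against 626 ± 135 (adjusted p = 0.0891 and 0.345). This call ended without IBA library 1, 3 or 5 or torpor library 1, 4 or 5 (adjusted p from 0.0607 to 0.163), and without torpor libraries 4 and 5 together the median was 0.01. Precursor, neuron, astrocyte and microglia markers did not pass as lists, with medians of 0.23, 0.22, 0.04 and 0.02 (adjusted p = 0.0971, 0.105, 0.623 and 0.470).

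Of 22 genes of the unfolded protein response, 2 rose and none fell, and 4 rose adjusted over the list alone (median 0.13, adjusted p = 0.0203, and adjusted p = 0.708 with an estimated correlation). Manf, a secreted factor of this response, rose to 131 ± 24.4 from 86.8 ± 11.1 and Selenos to 195 ± 25.4 from 150 ± 14.5 (adjusted p = 0.0206 and 0.0455). The list lost its call without IBA library 2 or torpor library 3 (adjusted p from 0.0681 to 0.0969), and under library-size scaling its median was 0.03. Manf lost its call without IBA library 2 or 3 or torpor library 3, and Selenos without any library except IBA library 5 and torpor library 1 (adjusted p from 0.0573 to 0.124). Of 22 heat shock chaperones none passed (median 0.02, mean −0.05, adjusted p = 0.862).

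Of 13 magnocellular neuropeptide genes none passed, also adjusted over the list alone, and the list passed (median 0.41, adjusted p = 0.0227, and adjusted p = 0.546 with an estimated correlation). Cartpt stood at 71.9 ± 47.6 against 22.2 ± 10.3 and Tac1 at 18.1 ± 8.05 against 9.72 ± 3.46 (adjusted p = 0.0784 and 0.138). The call ended without torpor library 4 (adjusted p = 0.0512), without torpor libraries 4 and 5 (0.135) and with the oligodendrocyte marker level in the model (0.0609). In the last 2 settings the median was 0.40 and 0.35. Of 23 genes of peptide processing none passed, also adjusted over the list alone (median 0.18, adjusted p = 0.0308, and adjusted p = 0.708 with an estimated correlation). Chgb, the secretory granule protein chromogranin B, stood at 1063 ± 250 against 857 ± 109, and Scg5, a chaperone of the prohormone convertase Pcsk2, at 860 ± 117 against 741 ± 93.5 (adjusted p = 0.271 and 0.302). That call ended without IBA library 3 or 4 or torpor library 3 or 4 (from 0.0629 to 0.115) and without torpor libraries 4 and 5 (0.0754, median 0.17), and under library-size scaling the median was 0.09. With the oligodendrocyte marker level in the model the median was 0.28 (camera adjusted p = 0.00489 with the preset correlation). Of 15 markers of neighbouring nuclei none passed, and 3 rose adjusted over the list alone (median 0.16, adjusted p = 0.0393, and adjusted p = 0.708 with an estimated correlation), among them Sst at 398 ± 197 against 181 ± 62.4 (adjusted p = 0.0842). The call ended without IBA library 1 or 5 or torpor library 4 or 5 (from 0.0648 to 0.137), without both of these torpor libraries (0.750) and with the oligodendrocyte marker level in the model (0.474). The median was 0.10 without both torpor libraries and 0.21 with the marker level in the model. Of 18 osmotic genes none passed, and 2 fell adjusted over the list alone (median −0.17, adjusted p = 0.120). Of 27 synaptic vesicle genes none passed, and 1 fell adjusted over the list alone (median 0.05, adjusted p = 0.490).

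Of 20 immediate early genes, Arc fell over all genes, and 2 rose and 3 fell adjusted over the list alone (median −0.25, adjusted p = 0.232). Of 21 cold-inducible and splicing genes, Clk1 and Clk4 fell, and 2 rose and 3 fell adjusted over the list alone (median −0.03, adjusted p = 0.862). Of 19 clock genes, 2 rose and 1 fell, and 3 rose and 2 fell adjusted over the list alone (median 0.07, adjusted p = 0.437). Bhlhe40 rose by 0.49 ± 0.11, and Nr1d2 fell by 0.48 ± 0.11 (adjusted p = 0.0221 and 0.0267). The call of Bhlhe40 ended without IBA library 2 or 5 (adjusted p at most 0.0530) and that of Nr1d2 without IBA library 1, 2 or 3 or torpor library 3 or 4 (at most 0.0722).

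The count of 455 was 159, 190, 238 and 268 without IBA libraries 3, 2, 1 and 5 and 202, 244 and 273 without torpor libraries 3, 2 and 4. It rose to 666 without torpor library 1. Over all alternatives, the lowest adjusted p of the 8 lists lay between 2.20e-24 and 0.00640 and the highest between 0.546 and 0.923.

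Changes in torpor and in IBA were compared because both were measured against the active state. Of the genes past the threshold in both, 77 were higher in both, 82 lower in both and 1 went in opposite directions, against 9 and 10.6 for independent lists of these sizes. Nop53 and C1qtnf4 were among those higher in both, and Kctd21 and Olfml2b among those lower in both. Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons correlated with r = 0.705 and covariance 0.0856. Both use the same active libraries, and simulated unchanged groups against shared controls gave r = 0.501 and covariance 0.0199, a difference in covariance of 0.0657. With the active libraries split so that the comparisons shared none, the median over 20 splits was 14 genes changed alike (3 to 72), with r = 0.465 and covariance 0.0659. The 159 genes changed alike became 83, 69, 61 and 54 without active libraries 1, 2, 3 and 4. Only active libraries were left out for this count. Without IBA library 4 only 26 genes passed in IBA against active, so at most 26 could be shared.

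Lists of receptors, channels and metabolism gave no call in any comparison, with camera adjusted p from 0.0730 to 0.980. In torpor against active, 4 of 23 glutamate receptor genes and 3 of 23 genes of GABA signalling rose and none fell (medians 0.19 and 0.15). Of 26 sodium, calcium and HCN channels 3 rose (median 0.10), and of 36 potassium channels 3 rose (median 0.01, mean 0.03, with the camera statistic pointing down). Of 25 hormone and neuropeptide receptors 1 rose and 4 fell (median −0.04), and of 29 genes of synaptic adhesion 2 rose and 1 fell (median 0.13). Of 21 glycolysis genes 1 rose and 2 fell (median 0.11), of 24 genes of fatty acid and ketone use 3 rose and 2 fell (0.08), of 20 cholesterol synthesis genes 3 rose and 1 fell (median −0.05, mean 0.09), and of 23 antioxidant genes 3 rose and 4 fell (0.08). Of 10 genes of thyroid hormone handling 1 rose and 1 fell (0.17), of 13 glucocorticoid-responsive genes 1 rose and 3 fell (−0.16), and of 18 inflammatory genes 1 rose and 2 fell (−0.10). Of 11 meningeal and fibroblast markers none passed (−0.60), and 1 each of 6 ependymal and choroid plexus markers and of 4 blood cell markers fell (−0.21 and −0.41).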

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

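The tests of the oligodendrocyte share, of a lower share of neurons, of the share of magnocellular neurons and of reads moved between loci were chosen only after the result was seen. The runs without torpor libraries 4 and 5, with the oligodendrocyte covariate and with other scalings were also added after seeing the data.

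Oligodendrocyte markers were higher in torpor than in the active state as a list (adjusted p = 0.583 with an estimated correlation), and that 92.3% of the measured markers had a positive log2 fold change restates this shift, so it does not decide whether the torpor dissections held a larger share of oligodendrocytes. A lower share of neurons that raises the markers of every other cell type alike is argued against, in that form only, by the mural list. Its median was −0.33, with members past the threshold, but its call was lost without any of 4 libraries and with an estimated correlation (0.583). Neuron markers did not shift downward (median 0.30, 3 of 13 risen and 1 fallen, camera adjusted p = 0.106). A lower share of neurons beside fewer vessel cells was not tested. Torpor libraries 4 and 5 had the highest marker levels. Without them the median was 0.80 with a standard error of 0.305. By a rule written before this run, but with the run itself added after the data were seen, a median of at least 0.601 spoke against these libraries alone as the cause. That rule named no margin for error. The median was not clear of this bound by its standard error, so how much of the shift rests on these libraries stays open. Whether the dissections took in more white matter or the cells themselves changed with the state cannot be told apart here.

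The locus LOC101970427 had a higher mean in torpor than in the active state (limma adjusted p = 0.0430, adjusted exact p = 0.143). Torpor library 1 lay within the active range. A larger share of magnocellular neurons is argued against by the log2 fold change of the locus lying 1.99 above that of Pdyn, the highest of the 3 genes compared (standard error 0.665). Reads moved from the 2 other measured loci are argued against as the whole cause, by a narrow margin: those loci lost 226.4 normalised CPM (standard error 1974) where this one gained 16540 (6330), and the 3 together rose by 16320 (7979), 2.05 standard errors. This test replaced one whose outcome had been seen, in which the gain exceeded the 9410 that those loci held in active libraries by more than 1 standard error but less than 2, read first as arguing against the explanation and then as leaving it open. The test of a single library was written before its result, for a locus chosen after its values were seen. It came out on the side of that explanation. Without active library 4, which stood below the other active libraries, the log2 fold change was 1.87, the lowest with 1 library left out, and the adjusted p 0.108, the highest. The adjusted p also passed 0.05 without any of 7 others (active 1, 2 and 5, torpor 2, 3, 4 and 5; from 0.0558), and without torpor library 4 the values were close to these (1.92 and 0.101), so the call does not hang on active library 4 alone. Within IBA and torpor the locus also followed the library pattern of Lsm4, Nop53 and Abtb1. A cause common to these genes was not tested.

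Subunits of oxidative phosphorylation and ribosomal proteins were higher in torpor than in IBA as lists, calls that ended with an estimated correlation (adjusted p = 0.546 and 0.708). A trend with expression level is argued against as the whole cause by medians at percentile 100 of 10000 lists matched on mean level. The central range of the matched medians lay above 0, at 0.02 to 0.13 and 0.009 to 0.12, so part of the shift may go with level. The matched lists held random genes, so this rank does not allow for the correlation within the 2 lists (0.40 and 0.63). Under the other scalings the lower median was 0.15 (spread 0.0133), on the side of the bound of 0.122 that speaks against library scaling. A larger share of oligodendrocytes is argued against by the lower median of 0.30 with the marker level in the model (spread 0.0215). Both spreads are smaller than the standard errors given above for single members. Those members are correlated, so the spreads do not cover the spread between libraries. The median under the other scalings lies near its bound, so how much of the shift rests on library scaling stays open. Bias from RNA quality or transcript length was not tested and stays open, so a change of these transcripts with the state may be put forward only as a hypothesis.

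Other splits of the libraries were tried for each count of genes, 100 drawn of 126. Only 1 of 100, the real split, gave as many genes in torpor against active (3018, highest other 5), 1 of 100 in IBA against active (202, highest other 1) and 1 of 100 in torpor against IBA (455, highest other 103, from IBA libraries 1, 2, 3 and 5 with torpor library 1). Chance is excluded at the 5% level for each.

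Of 582 groups of 5 libraries, 546 of them for 182 genes, 35 (6%) held a library far from the other 4 by Dixon's test, where chance alone gives about 1 in 20 (5%). Active library 4 accounts for 7 of them and IBA library 1 for 5. Active library 4 stood at 60.3 for Flt1 (others 46.1 to 48.4), 880.4 for LOC101970427 (3125 to 4983), 5.37 for Mag (31.6 to 41.3), 21.9 for Olig1 (27.5 to 30.2), 20.04 for Rab3a (65.7 to 79.5), 369 for Rplp1 (299.9 to 316) and 29.2 for Slc6a12 (9.67 to 12.1). Active library 3 stood at 133 for Ndufb11 (123 to 125) and 10.01 for Slc19a3 (12.8 to 14.01), and active library 5 at 7.26 for Myh11 (11.1 to 12.7). IBA library 1 stood at 104 for Dusp1 (41.8 to 54.5), 169 for Fos (23.5 to 38.4), 11.2 for Hspa1b (7.91 to 8.74), 14.9 for Nr4a2 (3.81 to 4.87) and 903 for Scg5 (683 to 740). IBA library 2 stood at 293 for Dnaja1 (410 to 454), 232 for Luc7l3 (194 to 201) and 138 for Ugt8 (82.8 to 89.4). IBA library 4 stood at 50.3 for Apln (22.5 to 28.4), 2.696 for C1qa (0.964 to 1.29) and 26.7 for Pecam1 (31.5 to 33.0), and IBA library 5 at 9.32 for Agtrap (11.2 to 11.8), 71.2 for Nfat5 (53.0 to 55.8) and 24.3 for Robo4 (44.0 to 52.2). Torpor library 1 stood at 9.26 for Kcnj2 (2.67 to 3.89) and 13.7 for Nrip3 (20.3 to 22.3), torpor library 2 at 1.87 for Znf526 (4.26 to 5.57) and 1.72 for Znf646 (5.26 to 6.85), and torpor library 3 at 20.7 for Ciart (34.7 to 37.9) and 9.33 for Nfe2l3 (13.4 to 15.03). Torpor library 4 stood at 18.3 for Fezf1 (29.6 to 35.8) and 132.5 for Znf331 (86 to 96.9), and torpor library 5 at 0.656 for Htr1e (3.34 to 4.99), 109 for Ndufb11 (124 to 129.8) and 8.15 for Nr4a1 (2.67 to 3.32).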

How the results depend on the processing

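The tests with edgeR's default settings, the other limma scalings, the oligodendrocyte covariate, and without torpor libraries 4 and 5 or unnamed loci were chosen only after the result was seen. Under the settings chosen beforehand, of 5000 values for named genes 4456 kept direction and side of the threshold, 437 fell short of it, 107 newly passed it and 0 reversed, and under the added ones 1243 of 1414 kept both. Of 2310 such list values 2172 kept both and 0 reversed, and of 595 added ones 555 kept both and 4 reversed. Of 142 such counts 103 stayed within 1.5-fold, and of 39 added ones 33.

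With the oligodendrocyte covariate the counts were 819 in torpor against active, 19 in IBA against active and 706 in torpor against IBA, with 6 lists in torpor against active and 17 shared genes. The covariate differed between the states, so calls that ended with it need not rest on oligodendrocytes. The median of the unfolded protein list in torpor against active reversed to 0.12 and the cause was not tested. The oligodendrocyte medians of 0.0492 (with the test pointing down), −0.0105 and −0.0299 follow from the construction, because the covariate is the mean of those markers.

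With only the 10 libraries compared the count rose to 385 in IBA against active, with 7 lists. It fell to 2294 in torpor against active and to 262 in torpor against IBA. The fit of all 15 libraries uses the same spread for every state. The lowest correlation between libraries of a state was 0.964 in torpor, 0.968 in active and 0.979 in IBA. Whether an unequal spread moved these counts was not tested. DESeq2 gave 866 genes in IBA against active, 1058 in torpor against IBA and 629 shared, with the higher false share of 14.1% on simulated data. Limma-voom gave 594 in IBA against active and 384 shared. Library-size scaling gave 859 in torpor against IBA. With an estimated correlation 0 lists passed in each comparison, against 10, 4 and 8 with the preset correlation (lowest adjusted p in torpor against active 0.583). Fry, which does not compare a list with other genes, called 10, 1 and 1. In torpor against active 6 of its 10 were among those called by camera: the unfolded protein, ribosomal, synaptic vesicle and mural lists lost their calls (adjusted p = 0.105, 0.264, 0.0881 and 0.0634), and the magnocellular neuropeptide, cold-inducible and splicing, GABA and glucocorticoid lists gained one (0.0295, 0.0295, 0.0356 and 0.0398, and 0.583 for each with an estimated correlation). The cause was not tested for these tools and scalings. With the active libraries split 14 genes were shared, where each comparison has fewer libraries. On these reads the default filter of edgeR removed none of the 16993 genes, so running it with no filter gives no further information.

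The replicate block gave 37 genes in IBA against active, 155 in torpor against IBA and 36 shared. The replicate numbers do not pair the libraries: of 15 pairs with the same number 3 correlated over 0.1 (−0.317 to 0.203), and 4 of 15 libraries correlated best with their own number, so the block removes degrees of freedom only.

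Leaving out each replicate in turn gave 2272 to 3310 genes in torpor against active, 26 to 165 in IBA against active and 159 to 666 in torpor against IBA. The lists numbered 9 to 13, 4 to 8 and 5 to 10. The shared genes were counted only with each active replicate left out, and numbered 54 to 120. Without IBA replicate 4 they could be at most 26. IBA against active fell to 26 without IBA replicate 4, and torpor against IBA to 159 without IBA replicate 3.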

Other observations

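The 39 families below were chosen after values were seen and are the only tests of this part, all of them chosen after the result was seen. In torpor, zinc finger and chromatin genes shifted downward. Of 39 Zbtb genes, transcription factors with zinc fingers, 15 fell and none rose in torpor against active (median −0.33, camera adjusted p = 5.92e-06 over 39 families, and 0.218 with an estimated correlation). Of 262 Znf and Zfp genes 60 fell and 19 rose (−0.18, 3.79e-04, and 0.218 estimated), and of 24 lysine demethylases and methyltransferases 9 fell and none rose (−0.25, 3.79e-04, and 0.218 estimated). Laminins, proteins of basement membranes, had 4 of 10 members lower (−0.42, 0.0387, and 0.662 estimated), and of 47 proteasome subunits 4 rose and 1 fell (0.14, 0.0387, and 0.943 estimated).

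In torpor against IBA these families were lower: Zbtb genes (4 of 39 fell, median −0.30, adjusted p = 1.17e-05, and 0.150 estimated), Znf and Zfp genes (14 fell and 2 rose, −0.14, 3.22e-05, and 0.150 estimated), demethylases and methyltransferases (3 of 24 fell, −0.16, 0.00112, and 0.266 estimated), laminins (0 of 10 past the threshold, −0.24, 0.0265, and 0.510 estimated), Integrator subunits (1 of 14 fell, −0.19, 0.00214, and 0.150 estimated) and Trim genes (2 of 38 fell, −0.11, 0.0386, and 0.499 estimated). Mitochondrial ribosomal proteins shifted upward, with 3 of 77 risen (0.17, 3.73e-08, and 0.499 estimated), as did proteasome subunits (0 of 47 past the threshold, 0.17, 1.28e-05, and 0.595 estimated), Lsm and Snrp genes (0 of 25, 0.18, 2.72e-04, and 0.419 estimated), mitochondrial translocases (2 of 22 risen, 0.17, 0.00214, and 0.587 estimated), vacuolar ATPase subunits (0 of 16, 0.13, 0.0130, and 0.595 estimated) and Ube2 genes (0 of 30, 0.09, 0.0384, and 0.419 estimated). In IBA against active only mitochondrial ribosomal proteins passed, with 0 of 77 members past the threshold over all genes by limma (−0.11, 0.0308, and 0.882 estimated). None of these medians changed sign under median-of-ratios or library-size scaling, but under library-size scaling the positive medians in torpor against IBA were smaller: 0.08 for mitochondrial ribosomal proteins, proteasome subunits and translocases, 0.10 for Lsm and Snrp genes, 0.04 for vacuolar ATPase subunits and 0.01 for Ube2 genes. The median of proteasome subunits in torpor against active was 0.06 under that scaling, and medians in torpor against IBA were larger in size for Znf and Zfp genes (−0.23), demethylases and methyltransferases (−0.25) and Trim genes (−0.18).

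The deposited log2 fold changes of LOC101970427 against active were 1.16 in IBA and 2.59 in torpor, with a joint false discovery rate of 0.0166 by the authors' test.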
